A study of Danio rerio with 4 samples.

How the data were processed

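Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out by the authors on 4 zebrafish embryo samples, 1 per group and none replicated. Sox2 was precipitated from wild-type embryos at the late blastula stage. Pou5f1 carrying a Flag tag was precipitated with an anti-Flag antibody from maternal-zygotic spiel ohne grenzen embryos, which lack functional Pou5f1, after injection of mRNA for the tagged protein, at the 512-cell stage and at late blastula. Input chromatin of wild-type late blastula embryos served as the control. Per the labels' protocols, chromatin was fixed with 1% paraformaldehyde, 20000000 nuclei went into each late blastula sample and 2000000 into the 512-cell sample. Per the series design text, sequencing was on the Illumina GAIIx, and Pou5f1 was run in technical duplicates to gain depth, without saying for which stage. CASAVA is named in the submitters' processing notes with no version. The aligner, the peak caller and the thresholds used are not given in the sources used here.

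The deposited files are peak lists, 1 per sample, so peaks were called by the authors for each sample and not on replicates. Per the file headers, each interval carries the count of reads inside it and the counts of forward and reverse reads, a false discovery rate in percent, a p-value named as a Wilcoxon filter, the accessions of a gene on each side, and a normalized difference. The last of these equals the absolute difference of forward and reverse reads as a fraction of all reads in the deposited interval, by recalculation. All of these are the authors' own values per peak. Reads and false discovery rates were used to rank and describe peaks within a list. The Wilcoxon filter p was also used to describe the lists side by side and, in 1 list, to compare strong peaks with and without Sox2. The coordinates are Zv9, the build named in the identifiers of the 3 late blastula lists. The 512-cell list names no build. Of its 836 intervals shared with the late blastula Pou5f1-Flag list, 779 (93.2%) had a flanking gene in common with it, and the same build was assumed. Starts were counted from 0 in the deposited lists and are given here counted from 1.

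The last numbers in the identifiers were 7362 for Sox2, 13010 for late blastula Pou5f1-Flag and 26225 for 512-cell Pou5f1-Flag, against 6129, 7130 and 7747 intervals listed, so the 3 ChIP lists hold a part of the numbered calls. The largest Wilcoxon filter p in those lists was 0.0500, whereas 1175 of the 1901 Input intervals had a p of 0.05 or more. The late blastula Pou5f1-Flag list runs through the chromosomes in 2 passes of 1217 and 5913 intervals, and 8 of its coordinates occur more than once. Both passes were kept, so some positions count more than once. Whether the passes are the technical duplicates is not given in the sources used here. Merging overlapping intervals left 6500 loci in that list, 6128 for Sox2, 7747 for 512-cell Pou5f1-Flag and 1901 for Input. Library totals were not analysed here. The reads inside intervals summed to 742542 for Sox2, 841679 for late blastula Pou5f1-Flag, 564835 for 512-cell Pou5f1-Flag and 966327 for Input, over 2576, 2939, 2471 and 2487 kb, and these sums are not depths. The precision of each share is therefore given by its exact binomial 95% interval over peaks or genes, which covers counting error only and says nothing of variation between embryos.

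A peak was counted as shared when it overlapped an interval of the other list by at least 1 bp, in each direction. The expected overlap came from 1000 random placements of the other list's intervals within their chromosomes, with a one-sided permutation p on positions. Chromosome ends were taken from the outermost interval of any list. Strength was the authors' read count per interval. Shared and unshared peaks of a list were compared by their medians and by the share of pairs in which the shared peak had more reads (AUC), with a two-sided permutation test of 100000 resamples. Peaks are not replicates. "Input-free" peaks overlap no Input interval.

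Gene names were matched from the RefSeq accessions through a RefSeq table of assembly GRCz12tu, which was used for names alone. Of the accessions named, 94.5% matched for Sox2, 95.1% for late blastula Pou5f1-Flag, 95.6% for 512-cell Pou5f1-Flag and 92.0% for Input. Others are given as accessions. Pairs of neighbouring peaks showed that the first gene column holds the gene at lower coordinates and the second that at higher coordinates, in 3061 pairs against 4, whatever the strand. The 11 gene lists, the tests, the rule for named genes and the first set of alternatives were fixed before the data were examined. A gene counted as having a peak when a list named it beside one. A peak can name a gene on each side, so neighbouring members of a gene list can be counted for the same peak. The test takes them as independent. The share of each list's measured genes with a peak was compared with that of all other genes among the 9679 named in any of the 4 files by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 44 tests (11 gene lists in 4 peak lists). A gene named in none of the 4 peak lists counted as not measured. Such a gene had no listed peak beside it or was missing from the gene columns. Shares of measured genes are therefore shares of genes with an interval in at least 1 peak list. Of 257 genes in the lists, 255 were found in the reference table. The distance of a named gene from its peak is not known here, and the genes listed beside a peak differ between lists (given with the results).

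Named peaks and genes followed a fixed rule. It took the 10 strongest Input-free peaks of each ChIP list, for each pair of lists the 5 shared Input-free peaks with the best lower rank and the 5 strongest unshared ones of each list, of each gene list up to 4 members with the strongest peaks and up to 2 without a peak in alphabetical order, and for each ChIP list the 5 genes with the most peaks. A member's strongest peak was taken as its best rank among Input-free peaks in any ChIP list. The reads given for a member are those of its strongest Input-free peak in each list, which need not lie at the same position. Positions present in all 3 ChIP lists, and further genes with many shared positions, were chosen after their values were seen.

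Alternatives covered the overlap rule (centres within 100 bp, reciprocal overlap of 50%, gaps of up to 500 bp), the stronger 50% of each list, equal list lengths, removal of Input peaks, chromosomes 1 to 25 alone, and the false discovery rate as strength. Added after seeing the data were merged intervals, each pass of the late blastula Pou5f1-Flag list alone, shifts of the other list's intervals by 10 to 50 kb, and other gene backgrounds. For the closing tests, genes were also placed on 1 map from the columns of all 4 lists, between the last peak that names a gene on its higher side and the first that names it on its lower side, leaving out genes whose bounds cross by over 200 kb. Alternatives to the overlaps used 200 placements. No Zv9 sequence or annotation was used here, so the planned positions of peaks relative to transcription starts, the planned windows around transcription starts and the planned search for Pou and Sox motifs were not run. The overlap and rank code was tested on simulated data made from the real Sox2 and late blastula Pou5f1-Flag lists. It found 1500 of 1500 planted positions, and 0 of 20 pairs of unrelated lists had p under 0.05. Those unrelated lists were placed at random, as in the test itself. They do not show how the placement p behaves for lists whose intervals cluster. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.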

Results

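Peaks of the transcription factors Sox2 and Pou5f1 were listed in zebrafish embryos around the onset of zygotic transcription. Sox2 is a SoxB1 factor, and Pou5f1 is the zebrafish relative of mammalian Oct4. The 4 groups were Sox2 at late blastula (6129 intervals, median 63 reads and 346 bp), Flag-tagged Pou5f1 at late blastula (7130 intervals, median 41 reads and 291 bp), Flag-tagged Pou5f1 at the 512-cell stage (7747 intervals, median 52 reads and 279 bp) and Input chromatin at late blastula (1901 intervals, median 72 reads and 459 bp). Each group held 1 sample, so no difference has a replicate check. The 512-cell sample came from 2000000 nuclei and the others from 20000000, and the number of listed peaks shows no change between stages by itself. All coordinates are Zv9, counted from 1, and each position is named by its flanking genes as listed, lower coordinate first. A position shared between lists is named from 1 of them, and another list can name other genes there. Whether a position is exonic, intronic or intergenic was not analysed here.

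The strongest Input-free Sox2 peak (955 reads, chromosome 17, 24111505 to 24112349) lay between b3gnt2b and otx1, a head homeobox gene. Others among the 10 strongest lay between vps13a and tcf7l1b, a Tcf factor of the Wnt pathway (785 reads, chromosome 8, 54433430 to 54434110), beside otx2a (756 reads, chromosome 1, 51431555 to 51432150) and between lbh and vox, a homeobox repressor on the ventral side (740 reads, chromosome 13, 54041738 to 54042356). Further members of the 10 were positions at tle3a and kif23 (876 reads), spag1a and pabpc1b (789 reads), an unnamed gene (NM_200017) and midn (739 reads), and a pair between suz12a and rab11fip4a (905 and 769 reads). One lay in the long stretch between met and zgc:113984 (924 reads). All 10 were also in the late blastula Pou5f1-Flag list.

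Whether Sox2 and Pou5f1 occupy the same places at late blastula was asked by the overlap of their lists. The shared positions with the best ranks in both lists were at romo1 and mych, a Myc family gene (599 Sox2 reads and 368 Pou5f1-Flag reads, chromosome 6, 50379167 to 50379890), at NM_200017 and midn (739 and 301 reads, chromosome 22, 18968373 to 18969143) and at oplah and foxh1, a partner of Smads in Nodal signalling (402 and 298 reads, chromosome 12, 14834843 to 14835523). Next were ndufa3 and ctnnb1, which encodes beta-catenin (417 and 280 reads, chromosome 16, 7452113 to 7452820), and epha2a and rbp7b (699 and 231 reads, chromosome 6, 45850476 to 45851231). Of the Sox2 peaks, 1766 (28.8%, exact 95% interval 27.7 to 30.0) overlapped a late blastula Pou5f1-Flag peak, and 2184 Pou5f1-Flag peaks (30.6%, 29.6 to 31.7) overlapped a Sox2 peak. The Pou5f1-Flag list counts some positions more than once, and with its overlapping intervals merged, a choice made after seeing the data, 1762 of 6500 loci (27.1%) had a Sox2 peak. Random placement gave 27.7 shared Sox2 peaks on average and 47 at most, a 63.7-fold excess (permutation p = 0.001, the smallest that 1000 placements give). With Pou5f1-Flag intervals moved by only 10 to 50 kb, an alternative added after seeing the data, the mean was 71.6 and the excess 24.7-fold. With the first pass of the Pou5f1-Flag list alone, 8.55% of Sox2 peaks were shared.

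The strongest Sox2 peaks without a late blastula Pou5f1-Flag peak lay at cyth4b and plxna1b (573 reads, chromosome 6, 979378 to 980167), slc48a1a and itga5 (524 reads), smarcd3b and plxdc2b (505 reads), nr5a1a and fgf17, an Fgf ligand gene (494 reads, chromosome 8, 54923873 to 54924476), and ccnh and tmem161b (479 reads). Those of late blastula Pou5f1-Flag without Sox2 lay at dusp14 and hnf1ba (1016 reads, chromosome 15, 15013047 to 15013555), trim23 and lpar1 (964 reads), slc49a3 and atp6v0e1 (826 reads), mstnb and pms1 (776 reads) and hrh2a and pcdh2g29 (752 reads). The remaining members of the 10 strongest were thbs4a and serinc5 (689 reads), dnal4b and si:dkey-179j5.5 (673 reads) and dus3l and cyp51 (598 reads), without Sox2, and klf2a and stil (856 reads, chromosome 22, 16044999 to 16046907) and NM_001114479 and egfl7 (597 reads), with Sox2. Of these 10 intervals, 6 were 505 to 509 bp long. Among the strongest 667 Input-free peaks of this list, 99 were 500 to 510 bp long, and of these 20.2% had a Sox2 peak, against 57.7% of the other 568 (Fisher's exact p = 3.0e-12, a test chosen after seeing the data).

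Which Pou5f1 positions of the late blastula were already present at the 512-cell stage was asked next. Positions shared at high rank were arpc2 and mettl5 (377 reads at late blastula and 408 at 512 cells, chromosome 9, 49096604 to 49097719), romo1 and mych (368 and 279 reads), NM_200017 and midn (301 and 240 reads), ndufa3 and ctnnb1 (280 and 223 reads) and cry2 and gnb5a (380 and 187 reads). The dusp14, trim23, klf2a, slc49a3 and mstnb positions were the strongest of late blastula without a 512-cell peak. In the other direction these were cd226 and cbln2b (566 reads, chromosome 24, 15088883 to 15089384), mir135c-1 and mfsd4aa (449 reads), hnrnpa0b and NM_001114881 (446 reads), irx1a and sim1a (435 reads) and vrtn and syndig1l (421 reads). Of the late blastula peaks, 995 (14.0%, 13.2 to 14.8) were shared with the 512-cell list, and 836 of the 512-cell peaks (10.8%, 10.1 to 11.5) with the late blastula list. These were 32.4 and 26.9 times the placed means of 30.7 and 31.0 (permutation p = 0.001 each, the smallest possible), and 21.2 and 16.7 times with the other intervals moved by 10 to 50 kb. With merged intervals 12.7% of late blastula loci were shared. Requiring centres within 100 bp lowered the shares to 9.10% and 7.03%, and the first pass alone held 2.85% of 512-cell peaks.

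Positions of 512-cell Pou5f1-Flag peaks that also had a late blastula Sox2 peak included several patterning genes. No Sox2 list of the 512-cell stage was analysed here. The best ranked were a site listed beside suz12a and rab11fip4a for Sox2 and beside grifin and lfng, a Notch-modifying enzyme gene, at 512 cells (905 and 386 reads, chromosome 3, 41903700 to 41904853), and the interval between vox and vent, paired ventral homeobox genes (617 and 316 reads, chromosome 13, 54056063 to 54056882). Then came sp5l, a Wnt target gene (442 and 343 reads), mych (599 and 279 reads) and etv4, an Ets gene of the Fgf pathway (406 and 334 reads). These names are those of the Sox2 list. In the 512-cell list the strongest Input-free peak beside etv4 had 93 reads and beside vent 192, so it does not name these genes at the positions given. The otx1, tle3a, tcf7l1b and lbh to vox positions, and the suz12a position of 769 reads, were the strongest Sox2 peaks without a 512-cell Pou5f1-Flag peak. The strongest 512-cell peaks without Sox2 were those at cd226, mir135c-1 and hnrnpa0b, together with mrpl38 and fbxl15 (503 reads) and mcm3 and serpinb1l4 (492 reads), of which the last 2 were in the late blastula Pou5f1-Flag list. The nudt1 and kdm8 position (357 reads) completed the 10 strongest at 512 cells. Of the Sox2 peaks, 571 (9.32%, 8.60 to 10.1) had a 512-cell peak, and 576 of the 512-cell peaks (7.44%, 6.86 to 8.04) had a Sox2 peak, 22.3 and 22.1 times the placed means (permutation p = 0.001 each).

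Positions in all 3 ChIP lists were 374 of 16960 Input-free loci (2.21%). By the lowest of their 3 ranks, the foremost were romo1 and mych, NM_200017 and midn, ndufa3 and ctnnb1, gldn and sema6d, oplah and foxh1, vox and vent, otx2a and mdh1aa, mycla and mfsd2aa, etv4 and ogfod3, and mpdu1a and sox19a. At sox19a, itself a SoxB1 gene, the reads were 255 for Sox2, 171 for late blastula and 241 for 512-cell Pou5f1-Flag (chromosome 5, 25866450 to 25867169). Sox2 and late blastula Pou5f1-Flag alone shared 1274 loci (7.51%), the 2 Pou5f1-Flag lists alone 390 and Sox2 with the 512-cell list alone 177. Single lists held 6620 (512-cell Pou5f1-Flag), 4089 (Sox2) and 4036 (late blastula Pou5f1-Flag). Among members of the gene lists, id1, a helix-loop-helix gene induced by Bmp, and tbxta, the notochord gene Brachyury, each had 7 Sox2 peaks shared with late blastula Pou5f1-Flag, and 4 of those at id1 were in the 512-cell list too. At vox 6 were shared and 5 were in all 3 lists.

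**Figure D1:**
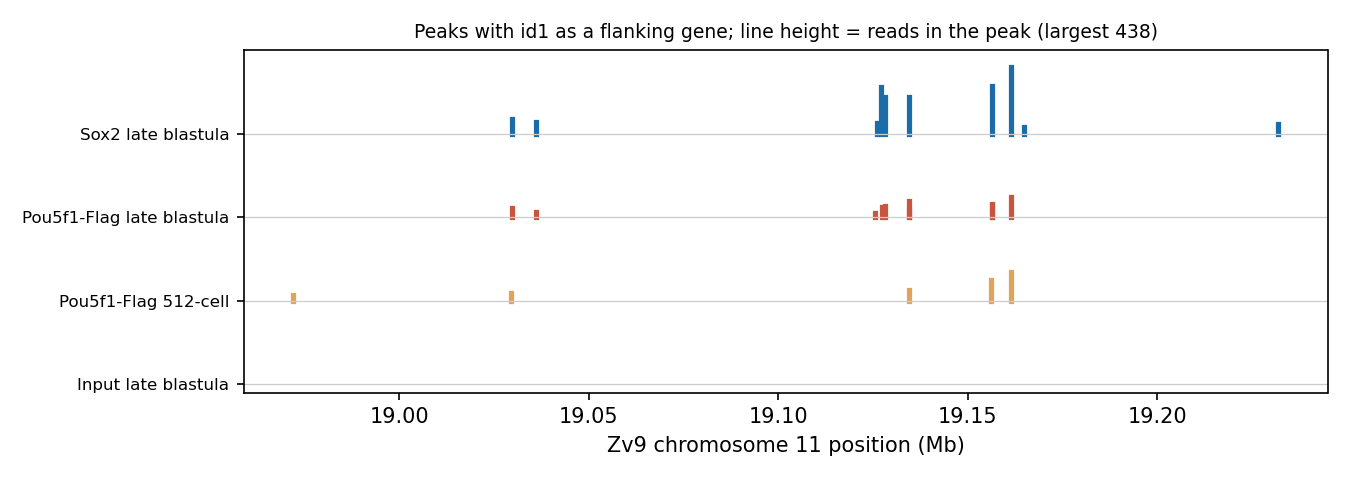
Peaks listed with id1 as a flanking gene on Zv9 chromosome 11 (position in Mb, horizontal), 1 line of marks per list, with the height of a mark proportional to its reads. Sox2 and late blastula Pou5f1-Flag each had 10 peaks, 512-cell Pou5f1-Flag had 5 and Input had 0, and the strongest Sox2 peak (438 reads, 19160938 to 19161648) had a counterpart in both Pou5f1-Flag lists (130 and 186 reads).

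Input chromatin of wild-type late blastula embryos gave the background. Its list was held to a looser bound than the ChIP lists. Its false discovery rate reached 23.5%, against 2.83% for Sox2, 2.77% for late blastula and 2.47% for 512-cell Pou5f1-Flag. Of its 1901 intervals, 1175 had a Wilcoxon filter p of 0.05 or more. No Input of the injected embryos or of the 512-cell stage was analysed here. Of the Sox2 peaks 205 (3.34%, 2.91 to 3.83), of late blastula Pou5f1-Flag 460 (6.45%, 5.89 to 7.05) and of 512-cell Pou5f1-Flag 174 (2.25%, 1.93 to 2.60) overlapped an Input peak. These were 13.1, 24.1 and 9.86 times random placement (permutation p = 0.001 each), but 4.32, 4.54 and 4.64 times once Input intervals were moved by 10 to 50 kb. Clusters of Input peaks lay around hpdb on chromosome 8, with 96 Input intervals. That gene had 59 Sox2 intervals, of which 17 were Input-free, and 97 of late blastula Pou5f1-Flag, of which 52 were. The neighbouring pbx3b had 95 late blastula Pou5f1-Flag intervals, of which 53 were Input-free. With centres within 100 bp the Input shares fell to 1.27%, 3.10% and 0.426%, in the order above.

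Stronger peaks were shared more often in every list. Sox2 peaks shared with late blastula Pou5f1-Flag, such as those at otx1, mych and foxh1, had a median of 110 reads against 53 for the rest (AUC 0.759), and those shared with 512-cell Pou5f1-Flag 125 against 60 (AUC 0.743). Late blastula Pou5f1-Flag peaks had 54 against 37 reads by Sox2 sharing (AUC 0.681) and 58 against 39 by 512-cell sharing (AUC 0.673). At 512 cells the medians were 92 against 51 (by Sox2, AUC 0.835) and 91 against 51 (by late blastula Pou5f1-Flag, AUC 0.830). Each permutation p was 1e-05, the smallest that 100000 resamples give. In 10 bins of equal size by reads, 73.9% (70.1 to 77.4) of the strongest Input-free Sox2 peaks and 6.08% (4.30 to 8.32) of the weakest were shared with late blastula Pou5f1-Flag. For 512-cell peaks shared with Sox2 the shares ran from 32.5% (29.1 to 35.9) to 0.396% (0.0818 to 1.15).

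**Figure D2:**
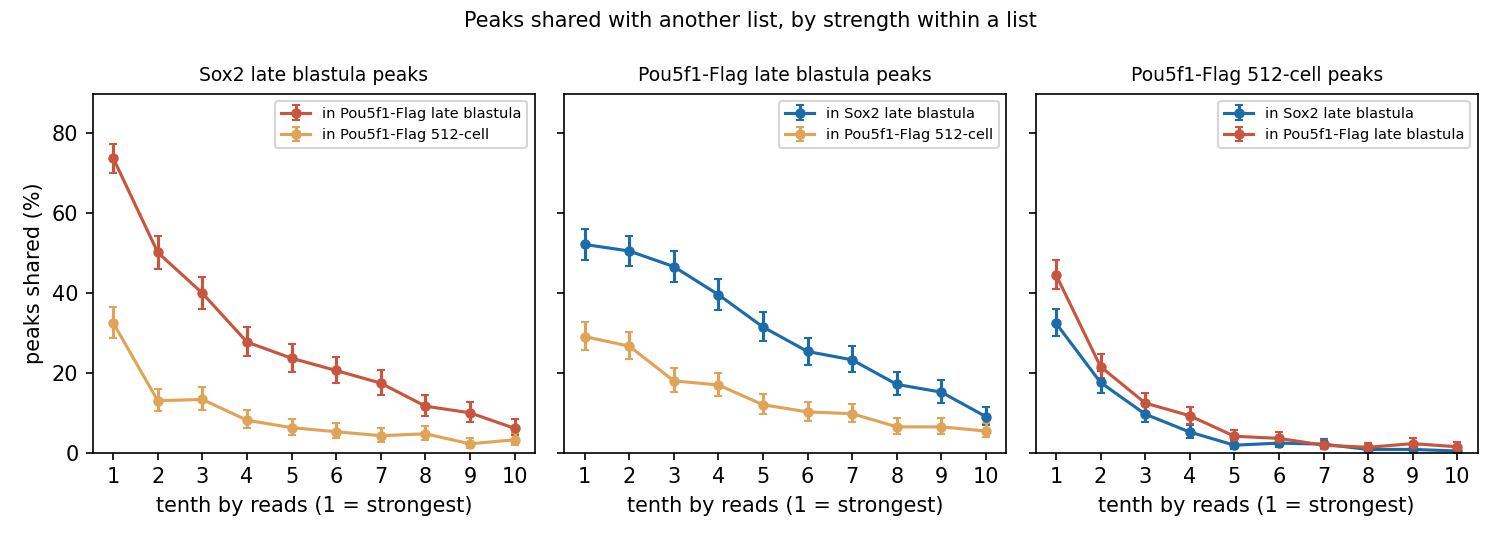
Share of Input-free peaks (percent, vertical) that overlap a peak of another ChIP list, in 10 bins of equal size from the strongest (1) to the weakest (10) by the authors' reads per peak, for each ChIP list, with exact 95% intervals. The share of Sox2 peaks with a late blastula Pou5f1-Flag peak runs from 73.9% to 6.08%, and that of late blastula Pou5f1-Flag peaks with Sox2 starts at 52.2%.

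Genes of early patterning were named beside Sox2 peaks more often than other genes, and those of the comparison groups were not. All 8 patterning lists passed the test for Sox2, 4 for late blastula Pou5f1-Flag, 2 for 512-cell Pou5f1-Flag and 0 for Input. Over the 8 lists, 144 of 163 measured genes (88.3%) had a Sox2 peak, 135 (82.8%) a late blastula and 135 a 512-cell Pou5f1-Flag peak, 17 (10.4%) an Input peak, and 107 a peak in all 3 ChIP lists. Of 41 measured genes in the 3 comparison lists, 17 (41.5%), 18 (43.9%) and 32 (78.0%) had a peak in these ChIP lists and 6 in all 3. Of the other genes named in any peak list, 51.6% had a Sox2 peak, 55.2% a late blastula Pou5f1-Flag peak and 73.0% a 512-cell peak. A gene list therefore had less room to stand out at 512 cells. These counts depend on the background: among the 7102 genes that the late blastula lists name, a choice made after seeing the data, dorsoventral and neural genes still passed for Sox2, neural genes for late blastula Pou5f1-Flag and Nodal and neural genes for 512-cell Pou5f1-Flag, while the other 6 Sox2 lists (exact adjusted p from 0.0928 to 0.433) and 3 late blastula Pou5f1-Flag lists (0.129 to 0.462) did not. The gene columns also differed between lists, as given for met and suz12a. A further comparison, also chosen afterwards, took peaks lying between late blastula intervals of the same gene pair. Of those absent from the 512-cell Pou5f1-Flag list, 12.1% of 2138 Sox2 and 8.55% of 2386 late blastula Pou5f1-Flag peaks lay beside a patterning gene. For peaks of the 512-cell list alone the share was 8.57% of 1715.

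Neural and ectodermal patterning genes passed the test in all 3 ChIP lists. Of 35 measured, 32 (91.4%) had a Sox2 peak (Fisher's exact adjusted p = 1.3e-05), 33 (94.3%) a late blastula Pou5f1-Flag peak (exact adjusted p = 1.3e-05) and 32 a 512-cell peak (exact adjusted p = 0.0380). For each gene, the reads here and below are those of its strongest Input-free peak in each list. These peaks need not lie at the same position. The strongest peaks were at otx1 (955 Sox2 reads, 163 late blastula and 66 512-cell Pou5f1-Flag reads) and gata2a, an ectodermal zinc finger gene (545, 95 and 78 reads in the same order). Next were the Hes-related repressor genes her3 (510, 97 and 191 reads) and her5 (487, 71 and 198 reads). The 955-read Sox2 peak beside otx1 had no 512-cell peak. In the Wnt list, 18 of 20 genes had a Sox2 peak (exact adjusted p = 0.00665), 17 a late blastula Pou5f1-Flag peak (exact adjusted p = 0.0264) and 16 a 512-cell peak (exact adjusted p = 0.824). Its strongest were tcf7l1b, with 785 Sox2 and 167 late blastula reads and no 512-cell peak, sfrp1a, which encodes a secreted Wnt antagonist (680, 222 and 123 reads), tcf7l1a (671, 141 and 59 reads) and sp5l (566, 163 and 343 reads).

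Fgf pathway genes had a Sox2 peak in 14 of 15 cases (exact adjusted p = 0.00930), a late blastula Pou5f1-Flag peak in 14 (exact adjusted p = 0.0159) and a 512-cell peak in 12 (exact adjusted p = 0.971). The Fgf ligand genes fgf17 (494 Sox2 reads), fgf8a (449) and fgf3 (416) and the Ets gene etv5a (418) led the list. The list of SoxB1, Pou and Klf factors also held nanog, foxd3 and the Myc genes mych, myca and mycn. Of all its genes, 14 of 16 had a peak in each ChIP list (exact adjusted p = 0.0211 for Sox2, 0.0344 for late blastula and 0.465 for 512-cell Pou5f1-Flag). Here mych, foxd3 (490, 93 and 131 reads) and sox2 itself (443, 137 and 98 reads) had their strongest peak for Sox2, and klf2a, a Krüppel-like factor gene, for late blastula Pou5f1-Flag (70, 856 and 80 reads).

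Nodal and mesendoderm genes had a Sox2 peak in 19 of 23 cases (exact adjusted p = 0.0159) and a 512-cell Pou5f1-Flag peak in 22 (exact adjusted p = 0.0344). With 17 the late blastula Pou5f1-Flag share did not pass (73.9%, exact adjusted p = 0.223). Foremost were foxa3 (410, 57 and 111 reads), foxh1, mixl1, an endoderm homeobox gene (76, 43 and 227 reads), and tbxta (381, 156 and 134 reads). Dorsoventral genes had a Sox2 peak in 17 of 20 cases (exact adjusted p = 0.0159), and 14 and 16 for late blastula and 512-cell Pou5f1-Flag (exact adjusted p = 0.465 and 0.824). They were led by vox, vent, bambia, which encodes a Bmp pseudoreceptor (473, 90 and 119 reads), and id1 (438, 130 and 186 reads).

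Notch and neural bHLH genes had a Sox2 peak in 14 of 15 cases (exact adjusted p = 0.00930) and a peak of either Pou5f1-Flag list in 11 (exact adjusted p = 0.396 and 1). The repressor gene her6 (441, 61 and 148 reads), the Delta gene dlc (302, 89 and 123 reads) and ascl1a (290, 108 and 85 reads) had peaks in all 3 lists, and the receptor gene notch3 (274 and 99 reads) had no 512-cell peak. With the stronger 50% of each list, the Notch share for Sox2 fell to 60.0% and no longer passed. Its members her1 and her7 had the same strongest reads for Sox2 (196) and late blastula Pou5f1-Flag (104), so the same peak may count for both. Adhesion and movement genes had a Sox2 peak in 16 of 19 cases (exact adjusted p = 0.0211), and 15 and 12 for late blastula and 512-cell Pou5f1-Flag (exact adjusted p = 0.116 and 0.528). The chemokine receptor genes cxcr4b (220, 97 and 248 reads) and cxcr4a (313, 144 and 128 reads) and the ephrin genes efnb2a (94, 49 and 215 reads) and efnb2b (99 and 185 reads, no 512-cell peak) led it.

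Housekeeping genes had a Sox2 peak in 5 of 15 cases, and 8 and 10 for the Pou5f1-Flag lists (exact adjusted p = 0.396, 1 and 0.804). The strongest were psmb1, a proteasome gene (134 and 218 reads, late blastula lists alone), b2m (135 Sox2 and 163 512-cell reads), ppiaa (37, 24 and 140 reads) and the beta-actin gene actb2 (119 reads, 512-cell list alone). Genes of differentiated tissues had 8, 8 and 14 of 16 (exact adjusted p = 1, 0.981 and 0.465), led by fabp10a of the liver (312 and 44 reads in the late blastula lists), myl1 of muscle, col2a1a of cartilage and prss1 of the pancreas. Germ plasm and oocyte genes had 4, 2 and 8 of 10 (exact adjusted p = 0.788, 0.139 and 1), led by ddx4, piwil1, cth1 and mos. Members named in no peak list, and so left out of these shares, included gdf6a, szl, gata6, tbx6, grhl1, irx3a, hey2, mib1, cxcl12b, epcam, atp5fa1, cox4i1, cpa5, cryaa, bmp15 and ccnb1. They may have had no peak or no entry in the gene columns. Measured were 15 of 24 housekeeping, 16 of 35 differentiated tissue and 10 of 20 germ plasm genes, against 35 of 40 neural genes.

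**Figure D3:**
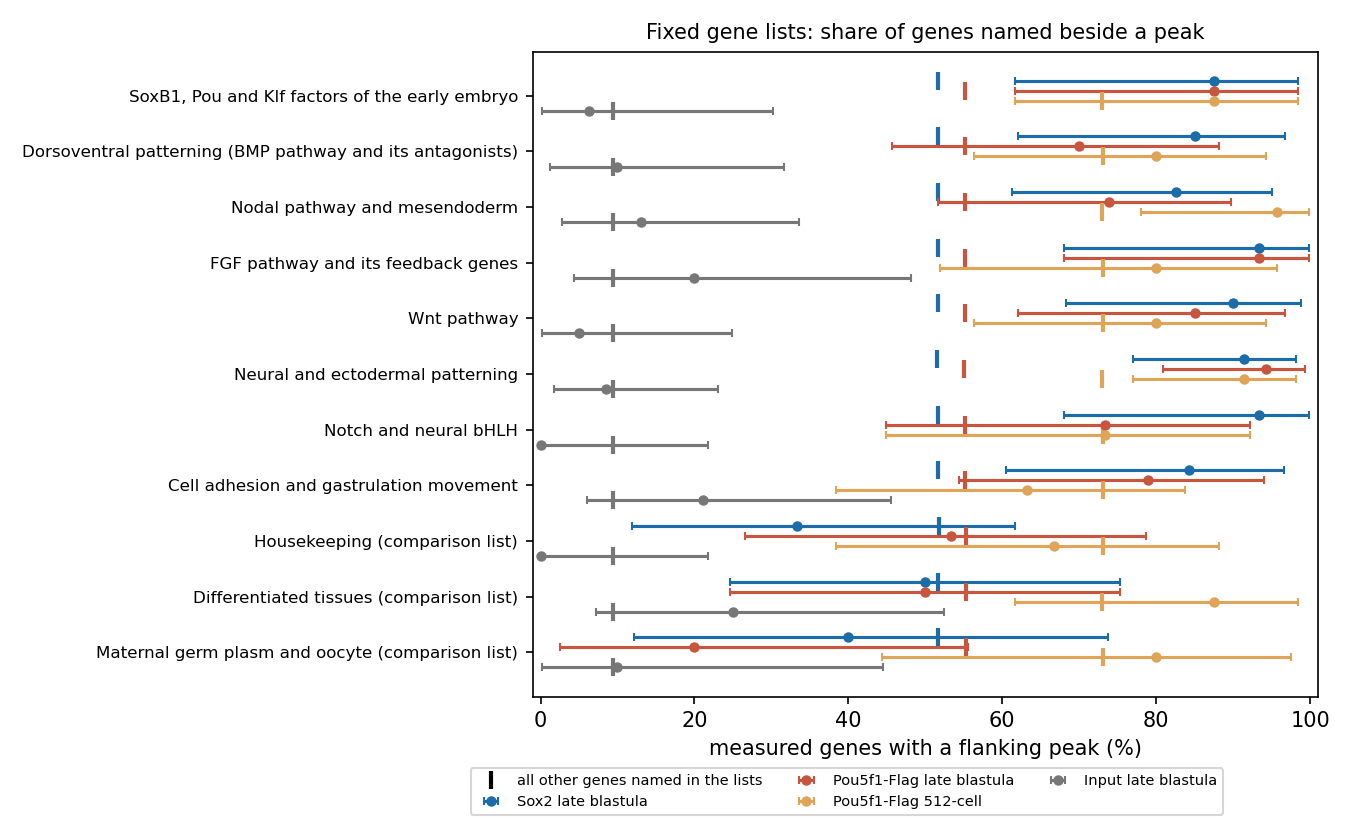
Share of the measured genes of each fixed list named beside a peak (percent, horizontal), with exact 95% intervals, for the 3 ChIP lists and Input. Upright marks are the shares of all other named genes. Neural and ectodermal genes lie at 91.4% for Sox2 against 51.5% of other genes, and housekeeping genes at 33.3%.

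The genes with the most Sox2 peaks were met and zgc:113984 (72 intervals each), suz12a (64), rab11fip4a (63) and hpdb, and those with the most late blastula Pou5f1-Flag peaks were hpdb, met and zgc:113984 (97 each), pbx3b and NM_001114900 (83). The Sox2 intervals between met and zgc:113984 spanned 17.1 Mb of chromosome 25, where the 512-cell list named 88 other genes, and those between suz12a and rab11fip4a spanned 8.04 Mb of chromosome 3, where it named 53. At 512 cells the genes with the most peaks were jkamp (24), abca5 (21), and mir2185-1, pnn and supt7l (20 each). Only 8 were Input-free for mir2185-1 and 8 for supt7l, whereas all were for jkamp, abca5 and pnn. By coordinates alone the mir2185-1 intervals ran over 27509 kb, and whether all of them lie on chromosome 1 was not tested.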

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

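The comparison of the strongest 500 peaks, the stage difference and the test of interval lengths were chosen after the results were seen. Counts of late blastula Pou5f1-Flag peaks in this section include positions listed more than once, which the intervals and p-values do not allow for.

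The p-value that the files name as a Wilcoxon filter was not part of the overlap, strength or gene list comparisons, and its low values stood above the control in both late blastula lists. It was under 1e-05 in 55.8% (exact 95% interval 54.5 to 57.0) of Sox2 peaks and 11.3% (10.6 to 12.1) of late blastula Pou5f1-Flag peaks, against 7.16% (5.40 to 9.29) of the 726 Input peaks that pass the same bound. For 512-cell Pou5f1-Flag it was 7.06% (6.50 to 7.65). Of the 10 strongest Sox2 peaks, such as those at otx1, tcf7l1b and vox, all were listed with a p of 0.

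The Pou5f1-Flag lists differed between the stages in how often they met Sox2. Of Input-free peaks, 31.0% (n = 6670) at late blastula and 7.32% (n = 7573) at 512 cells had a Sox2 peak, a difference of 23.7 percentage points (22.4 to 25, Fisher's exact test p = 5.4e-302, over peaks). With overlapping late blastula intervals merged, Input peaks included, 27.1% of 6500 loci had a Sox2 peak. Weak peaks at the end of the 512-cell list do not account for all of the difference. Among the strongest 500 of each list the shares were 49.8% and 34.6%, a difference of 15.2 points (9.09 to 21.1), though repeated positions were not merged there. Stage cannot be told apart from the number of nuclei or the library, because these go together in the 2 samples, and the Sox2 list is itself of late blastula. The 512-cell positions that Sox2 shared were, by the genes named in the Sox2 list, at genes such as vox, vent, sp5l and etv4.

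Strong late blastula Pou5f1-Flag peaks without Sox2, such as those at dusp14, trim23 and mstnb, made up 319 of the strongest 667 Input-free peaks. A Wilcoxon filter p of 0.001 or more was found in 63.9% of them and in 19.8% of the 348 with a Sox2 peak, a difference of 44.1 points (37.1 to 50.5). Intervals of 500 to 510 bp met Sox2 less often than the rest, with a difference of -37.5 points (-45.4 to -27.7), so reads piled on a few positions may account for part of these peaks. Strong peaks without Sox2 were in the 512-cell list in 17.9% of cases against 39.4%, a difference of -21.5 points (-28.0 to -14.7). Equal or higher shares had been predicted for Pou5f1 sites that Sox2 does not share. A split not planned beforehand took peaks with a Wilcoxon filter p under 0.001. Of these, 21.7% of 115 without Sox2 and 39.8% of 279 with it were in the 512-cell list. Over all Input-free late blastula Pou5f1-Flag peaks, Sox2 met 54.6% of those in the 512-cell list and 27.2% of the others. The 2 kinds of sharing went together, so the lower share cannot decide whether the strong peaks without Sox2 are Pou5f1 sites. Over all late blastula Pou5f1-Flag peaks random placement gave 0.431%, so the 17.9% is not at that level, and some may be sites held at both stages. Sites that Pou5f1 takes up without Sox2 only by late blastula stay open, and were not tested.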

How the results depend on the processing

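Merged intervals, single passes of the late blastula Pou5f1-Flag list, shifts of 10 to 50 kb and the other gene backgrounds were chosen after seeing the data. Of 68 recomputed overlap values, 57 stayed within 1.5 times the reported value, 11 moved further and 0 fell to the level of random placement. Shifts by 10 to 50 kb, counted apart, moved the chance count by more than 1.5 times in 7 of 9 overlaps, for Sox2 with late blastula Pou5f1-Flag from 27.7 to 71.6. All 12 recomputed strength comparisons kept their direction and passed. No overlap, strength comparison or gene list past its threshold reversed, and in 11 gene list tests that passed in neither setting the share changed side of the other genes. Merging intervals gave 27.1% of late blastula Pou5f1-Flag loci with Sox2 and 12.7% with a 512-cell peak. Requiring centres within 100 bp gave 9.10% of late blastula Pou5f1-Flag peaks shared with 512 cells, 7.03% in the other direction, and Input shares of 1.27% (Sox2), 3.10% (late blastula) and 0.426% (512-cell). Reciprocal overlap of 50% gave Input shares of 1.52%, 3.55% and 0.361%. Both rules are stricter by construction. The first pass alone, with 1217 intervals, left 8.55% of Sox2 and 2.85% of 512-cell peaks shared. The stronger 50% of the 512-cell list met the stronger 50% of Input in 3.69%, and the cause was not tested. Against the 7102 genes named in late blastula lists, 2 patterning lists passed for Sox2 and 1 for late blastula Pou5f1-Flag, and 9 of 14 calls ended. That background leaves out genes that no late blastula list names, whether for want of a peak or through the gene columns. Which of these ended the calls was not tested. Against 16147 genes, which include genes named in no list, 8 lists passed for late blastula and 6 for 512-cell Pou5f1-Flag. With the stronger 50% of peaks 7 passed for late blastula Pou5f1-Flag, and the Notch genes no longer did for Sox2 (60.0%, exact adjusted p = 0.0702). Without Input peaks all 33 tests kept their side of the threshold. Alternatives on positions, windows around transcription starts and motifs were not run, for want of a Zv9 genome here. What depth limits could not be tested, since library totals were not analysed here.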

Other observations

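All tests in this part were chosen after the overlaps were seen, except the odds ratios of 2.39 and 1.65.

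Positions held by Pou5f1 at both stages met Sox2 more often than positions of a single stage. Of Input-free late blastula Pou5f1-Flag peaks also listed at 512 cells, 54.6% (n = 940) had a Sox2 peak, against 27.2% of the 5730 others, a difference of 27.4 points (24.0 to 30.8, Fisher's exact test p = 3.5e-59). Of 512-cell peaks also listed at late blastula, 48.3% (n = 775) had one, against 2.65% of 6798, a difference of 45.6 points (42.1 to 49.1, exact p = 1.0e-268). The positions that the Sox2 list names beside mych, foxh1, vox, otx2a and sox19a belong to this shared set. The 512-cell list names foxh1 beside 1 interval of 68 reads, not beside the interval of 167 reads at this position. Shared peaks are also stronger, and these shares were not adjusted for strength. The late blastula list also repeats positions, which the intervals and p-values do not allow for. Merged over the ChIP lists, 374 Input-free loci in both Pou5f1-Flag lists had Sox2 and 390 did not. Of loci in the late blastula but not the 512-cell Pou5f1-Flag list, 1274 had Sox2 and 4036 did not. In the reverse case 177 did and 6620 did not. In a separate count that does not bear on this, 49 of the weaker 3787 peaks at 512 cells had a Sox2 peak, against 11.3 by random placement and 20 at most (permutation p = 0.005, the smallest of 200 placements).

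The patterning genes may owe part of their count to wide gaps between genes, which collect more peaks. Sox2 peaks absent from the 512-cell list lay beside a patterning gene in 9.86% of cases and late blastula Pou5f1-Flag peaks in 7.05%, against 4.38% of 512-cell peaks in neither late blastula list. With gaps resampled, the odds ratios were 2.39 (1.95 to 2.95) and 1.65 (1.34 to 2.07). Intervals holding 1 had been predicted if gap width were the cause. Gap width was not measured, and whether 512-cell peaks fell in gaps by width is not known, so these ratios cannot decide on it. Since the gene columns differ between lists, 1 gene map was built from the columns of all 4 lists and used for every peak. The ratios were then 2.49 (2.05 to 3.03) and 1.69 (1.38 to 2.09), no lower than with the columns as listed. The map was itself made from those columns. It kept both listed genes for 85.3% of Sox2, 81.8% of late blastula and 73.0% of 512-cell Pou5f1-Flag intervals. For these reasons it cannot decide whether the columns play a part. Among peaks lying between late blastula intervals that named the same gene pair, 2138 for Sox2, 2386 for late blastula Pou5f1-Flag and 1715 at 512 cells, the ratios were 1.47 (1.07 to 2.03) and 0.996 (0.727 to 1.40) with the columns as listed and 1.43 and 0.968 with that pair, but these peaks were selected by late blastula peaks nearby. A preference of the factors for patterning genes is a hypothesis, and for Pou5f1 no excess was seen in that selected set.

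The passes of the late blastula Pou5f1-Flag list differed from each other. Of the first, 627 of 1217 intervals (51.5%) overlapped the second, and of the second 625 of 5913 (10.6%) overlapped the first. Sox2 peaks met 67.0% of first-pass intervals that were in both passes and 17.3% of those in the first alone. In the second pass these shares were 68.3% and 23.4%. Input peaks met 20.5% of the first pass and 3.57% of the second. Mitochondrial intervals numbered 2 for Sox2, 2 for late blastula Pou5f1-Flag, 0 for 512-cell Pou5f1-Flag and 14 for Input.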
